A study of Trametes cinnabarina with 16 samples.

How the data were processed

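RNA from cultures of the white-rot basidiomycete Pycnoporus cinnabarinus (also named Trametes cinnabarina), strain PB94, was sequenced in 16 libraries. The cultures had no added energy source (control, 3 libraries), cellobiose (3), glucose (1), maltose (3), poplar (3) or switchgrass (3). Per the labels' protocols, the control and soluble-sugar libraries were prepared from poly-A RNA and the poplar and switchgrass libraries from RNA depleted of ribosomal RNA, so 10 libraries had the first preparation and 6 the second. Every comparison of a plant substrate with control therefore also compares preparations. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

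The authors deposited a pair of tables of 45286 assembled transcripts, both in TPM, a transcript abundance corrected for length and scaled to a total of 1000000 in every library. One of them is presented as holding expected counts, but each of its columns summed to 1000000 within 0.87, and the values were treated as TPM. RSEM is named in the submitters' processing notes; its version, the assembler, the aligner and any filters are not given in the sources used here. TPM keeps no read depth, so the depth of each library is unknown and no counting interval could be given. A value of 0 may be a failed estimate and is reported only as listed at 0.

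The deposited TPM tables hold identical values in 16 of 16 columns, but 0 of the 16 columns carry the same name in both. The names of the table presented as holding expected counts were used throughout. Under those names the columns of the other table stand in the order of the sample records (16 of 16), and libraries correlate more on average within a stated preparation than across preparations. The third maltose library correlates less than others with both preparations, but more with the other poly-A libraries (mean 0.599) than with the rRNA-depleted ones (0.518). Its mean with the poly-A libraries is below the mean across preparations over all libraries (0.673). This choice was made after the values were seen and is not settled by the tables. An earlier form of the correlation test went the other way, and correlation within groups can hardly tell the names apart (given in the closing section). Every group label below, and the direction of every comparison, depends on this choice.

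Isoforms were summed to 27990 assembly genes, and the 23981 with at least 1 TPM in at least 3 libraries were tested. The main test was limma (version 3.58.1, R 4.3.3) with an intensity trend on log2(TPM + 1), fitted to all 16 libraries as 6 group means, with Benjamini-Hochberg adjustment over the genes of a comparison and calls at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes; each is given with its standard error (SE). Before the data were examined a count-based test had been fixed as the main one and this test as an alternative. Because the tables hold no counts, this test became the main one before any test was run. The spread of the lone glucose library was assumed to be that of the other groups. With 3 libraries against 3 there are 10 splits, so an exact test of one gene cannot give a p below 0.1. Permutation tests of single genes were therefore not run.

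No identifier matched the reference list of 10441 genes (0 matches) and the tables pair no names with their identifiers, so the 26 gene lists fixed beforehand could not be evaluated (0 of 26). The rule for named genes was the 2 largest rises and the 2 largest falls of each comparison among called genes above the median level whose replicates do not overlap between the groups. Genes chosen after their values were seen are marked so.

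The test was tried on simulated libraries with known changes before the deposited values were tested. Every simulated library of a gene had the same spread, pooled over all groups with the third maltose library included. The changed genes were drawn from those above the median level. In the simulation of cellobiose against control (22636 genes) it found 0 of 50 genes changed 4-fold, 6 of 50 changed 8-fold and 15 of 50 changed 16-fold, with 1 false call. In the simulation of switchgrass against poplar (22661 genes) it found 1 of 50 at 8-fold and 4 of 50 at 16-fold. For glucose against control (22602 genes) it found 0 of 50 at 16-fold. A gene that was not called was therefore not shown to be unchanged. The deposited libraries are not alike in spread, so these shares and the count of false calls may not hold for them.

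The alternatives were another pseudocount, fits to fewer libraries, the replicate number as a block and each library left out in turn. Alternatives chosen after the data were seen were median-of-ratios scaling, other filters on low values, a test against a 1.5-fold change, tests of transcripts, the second table's column names, weights per library and fits without the third maltose library. Counts of alternatives given for a named gene leave out the library weights, whose estimation did not converge, and the tests of transcripts. Between-comparison overlaps were set beside 20 simulations of unchanged groups against the same controls. In them every library of a gene had the same spread, pooled over all groups with the third maltose library included. A correlation near 0.5 then follows from the shared libraries alone. The contrasts glucose against maltose and cellobiose against glucose were also tried after the data were seen.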

Results

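Expression was measured as TPM in 16 libraries of strain PB94, in 6 groups of 3 libraries except glucose, which had 1. Depth is unknown for every library. Between 22.8% and 67.3% of the 45286 transcripts were listed at 0. In the poly-A libraries other than the third maltose library, the 10 most abundant genes of a library held 6.57% to 12.7% of its TPM. They held 83.7% in the third maltose library, 75.3% in the second poplar library and 50.8% in the third switchgrass library. The third maltose library also correlated least with its own group (mean Spearman correlation across genes 0.574, against 0.751 and 0.754 for the other maltose libraries). The last 2 means each include the correlation with the third maltose library, which lowers them. Group names follow one of a pair of tables whose column names disagree, and under the other names most directions given here for the plant substrates turn around.

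**Figure D1:**
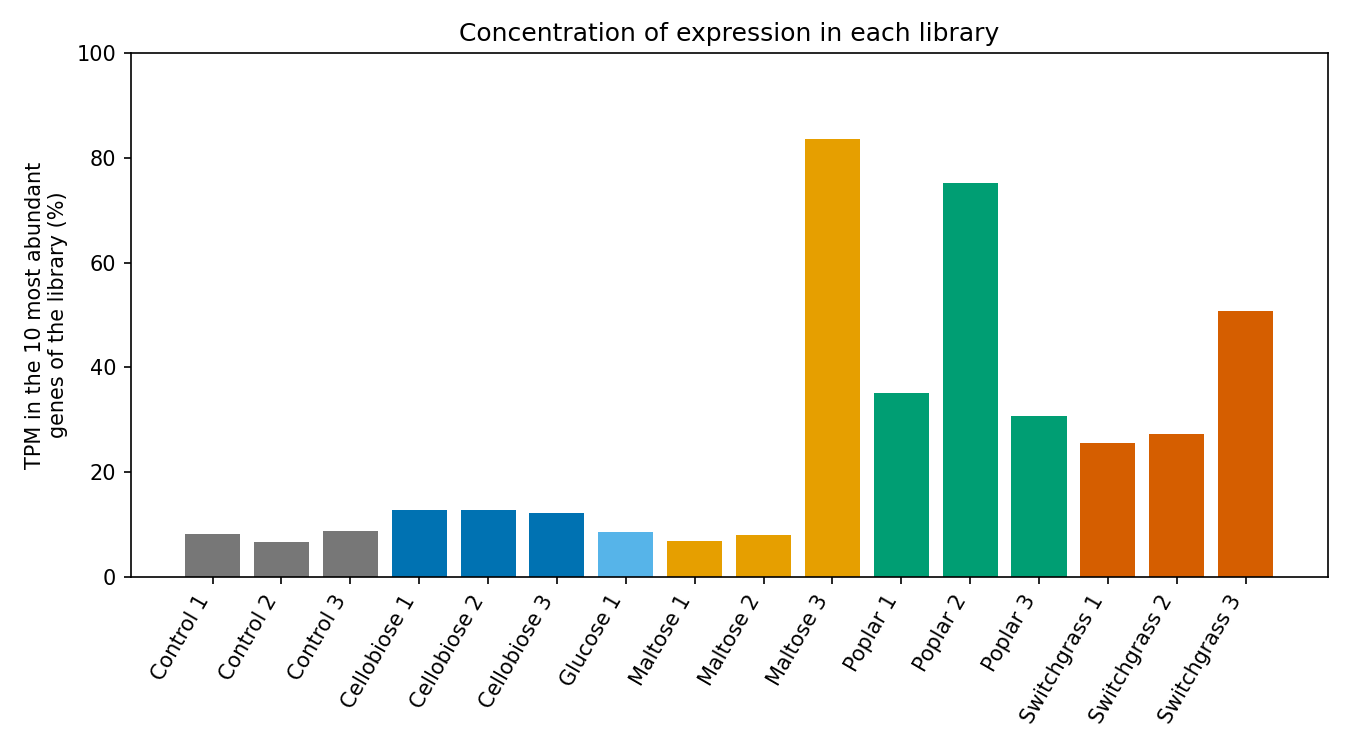
Bars give the percentage of each library's TPM held by its own 10 most abundant genes (vertical axis, percent; 16 libraries, colours by group). The third maltose library (83.7%) and the second poplar library (75.3%) stand above the others.

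Growth on cellobiose, a disaccharide released from cellulose, was compared with growth without an energy source. In cellobiose 48 genes were higher and 19 lower. The 48 genes had a median of 63.5 TPM in cellobiose and 2.69 in control, and 4.01, 2.07, 1.17 and 2.80 in glucose, maltose, poplar and switchgrass; together they held 2.41% of TPM in cellobiose and 0.0368% in control. TR5320__c0_g1 was at 8449 ± 905 TPM (SD, n = 3) in cellobiose and 39.7 ± 19.2 in control, and TR15638__c0_g1 was at 3124.5 ± 115.1 and 19.8 ± 4.40. The 19 lower genes had a median of 1.82 TPM in cellobiose, 38.8 in control and 2.70 in the glucose library. Among them TR4168__c0_g1 was at 2.65 ± 0.456 TPM in cellobiose and 195 ± 52.1 in control. TR11619__c0_g1 was listed at 0 in all 3 cellobiose libraries and the glucose library, and at 46.6, 63.9 and 58.5 TPM in the control libraries.

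The limma log2 fold changes were 7.79 ± 1.55 (SE) for TR5320__c0_g1 (adjusted p = 0.0338), 7.25 ± 1.02 for TR15638__c0_g1 (adjusted p = 0.00159) and -5.72 ± 1.20 for TR4168__c0_g1 (adjusted p = 0.0468). For TR11619__c0_g1 the adjusted p was 0.00263, and no fold is given against a group at 0. The replicates of both groups did not overlap in 32.0% of the tested genes, where chance gives at most 10%. The count of 67 became 33, 20 and 23 without the first, the second and the third cellobiose library and 25, 22 and 22 without the first, the second and the third control library, and 314 (168 higher, 146 lower) without the third maltose library. A pseudocount of 0.1 gave 9 (4 higher, 5 lower), and a fit to the 2 groups compared gave 3197 (1466 higher, 1731 lower). With median-of-ratios scaling the count was 173 (101 higher, 72 lower), of which 46 were among the 67. Under the second table's names it was 43, of which 4 were among the 67. The call of TR5320__c0_g1 was lost in 11 of 16 alternatives, that of TR4168__c0_g1 in 12, that of TR15638__c0_g1 in 2 and that of TR11619__c0_g1 in 1.

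Maltose, a disaccharide from starch, was compared with control in the same preparation. The called change was a fall of TR14662__c0_g1, listed at 0 in all 3 maltose libraries and at 13.15, 14.13 and 9.66 TPM in the control libraries; it was also listed at 0 in the 6 plant libraries, and was named after its values were seen. No gene was called higher (limma, 1 call in all; 1521 genes at an unadjusted p under 0.05). Without the third maltose library 903 genes were higher and 45 lower. Those 903 genes held 9.38% and 14.1% of TPM in the first and second maltose libraries and 0.0135% in the third, and 2.32%, 0.582% and 0.214% in the 3 control libraries. With the 10 most abundant genes of the third maltose library set aside, they held 9.45%, 14.5% and 0.0827% in the maltose libraries.

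The adjusted p of TR14662__c0_g1 was 0.0300. Its call ended without the first or second maltose library or any single control library, which left 0 calls each time, and it ended in 11 of 15 alternatives. The median log2 fold change of all tested genes was -0.61, against -0.06 with median-of-ratios scaling (10 calls, 7 higher and 3 lower) and -0.08 without the third maltose library (948 calls); under the second table's names 9206 genes were called.

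Cellobiose and maltose were compared directly, as disaccharides of glucose that differ in their linkage. In cellobiose 106 genes were higher and 10 lower than in maltose. The 106 had a median of 126 TPM in cellobiose, 3.42 in maltose and 9.09 in control and held 9.46% of TPM in cellobiose, 0.232% in maltose and 0.560% in control. Of these genes 44 were also among the 48 called higher against control, in a comparison that uses the same cellobiose libraries, so overlap is built in (correlation of the fold changes across genes 0.583, and 0.502 in simulations of unchanged groups). TR5320__c0_g1 was listed at 20.5, 41.2 and 0 TPM in the maltose libraries and TR15638__c0_g1 at 11.6, 15.5 and 0. TR6397__c0_g1 was at 199.7 ± 36.6 TPM in maltose and at 41.4, 1.36 and 0.85 in the cellobiose libraries. TR14927__c0_g1 was at 71.2, 62.7 and 8.94 TPM in the maltose libraries and 0.553 ± 0.586 in cellobiose. In control TR6397__c0_g1 was at 153.9 ± 38.1 TPM and TR14927__c0_g1 at 39.9 ± 14.8, and in the glucose library they were at 172 and 68.9.

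The limma log2 fold changes were 9.77 ± 1.55 for TR5320__c0_g1 (adjusted p = 0.00300), 9.04 ± 1.02 for TR15638__c0_g1 (adjusted p = 9.79e-05), -5.12 ± 0.98 for TR6397__c0_g1 (adjusted p = 0.0144) and -4.59 ± 0.93 for TR14927__c0_g1 (adjusted p = 0.0252), of which the last lost its call in 9 of 15 alternatives, TR6397__c0_g1 in 4, TR5320__c0_g1 in 2 and TR15638__c0_g1 in 1. Without the third maltose library all but 1 of the 116 genes were still called, but 1456 were called in all, 226 higher and 1230 lower in cellobiose, and the log2 fold changes were 8.13 for TR5320__c0_g1 and 7.76 for TR15638__c0_g1. The count of 116 was 70, 49 and 47 without the first, the second and the third cellobiose library, and scaling gave 120 higher and 53 lower and moved the median of all tested genes from 0.65 to 0.10 on the log2 scale. Under the second table's names 7912 genes were called, 1558 higher and 6354 lower.

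Poplar, a woody substrate, was compared with control; these groups also differ in library preparation. In poplar 531 genes were higher and 2063 lower. The 531 genes had a median of 34.4 TPM in poplar, 34.8 in switchgrass and 0.807 in control, and held 57.6% of TPM in poplar and 0.447% in control. TR355__c0_g1 was at 13764, 4746 and 11706 TPM in the poplar libraries and 1.88, 1.91 and 0 in the control libraries. TR15843__c0_g1 was at 20184, 2215 and 854 TPM in poplar and listed at 0 in all 3 control libraries. TR17256__c0_g1 was at 1.67 ± 1.35 TPM in poplar and 2993 ± 1129 in control, and TR5381__c0_g1 at 1.04 ± 0.938 and 2163 ± 861. Both genes were also below control in the sugar groups. Their means were 279 and 196 TPM in cellobiose, 576 and 367 in the glucose library, and 641 and 445 in maltose. The 10 most abundant genes of the plant libraries, which were chosen by their level in these libraries and so are high there by choice, held 43.7% ± 23.6 of TPM in poplar and 0.492% ± 0.137 in control.

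The limma log2 fold changes were 12.14 ± 0.90 for TR355__c0_g1 (adjusted p = 8.56e-08), -10.19 ± 1.08 for TR17256__c0_g1 (adjusted p = 7.00e-06) and -10.08 ± 1.02 for TR5381__c0_g1 (adjusted p = 4.00e-06); TR15843__c0_g1 had an adjusted p of 8.56e-08 and no fold is given. The split between directions depended on the scaling and on single libraries. With median-of-ratios scaling 2645 genes were higher and 1205 lower, and the median of all tested genes moved from -0.73 to 0.22 on the log2 scale. The count of 2594 was 873 without the first poplar library, 858 (465 higher, 393 lower) without the second, 715, 660 and 883 without the first, the second and the third control library, and 8435 (879 higher, 7556 lower) without the third maltose library. Scaling without that maltose library gave 3517 higher and 3777 lower. Under the second table's names all 4 named genes were called in the opposite direction.

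Switchgrass, a grass substrate, was compared with control under the same difference in preparation. In switchgrass 624 genes were higher and 1137 lower. The 624 genes had a median of 30.9 TPM in switchgrass, 18.2 in poplar and 0.763 in control. TR355__c0_g1 was at 37101, 27155 and 8379 TPM in the switchgrass libraries. TR14277__c0_g1 was listed at 0 in all 10 poly-A libraries, at 7988.5, 6007 and 4474 TPM in switchgrass, and at 7392, 0 and 6670 in poplar. TR17256__c0_g1 was at 5.43 ± 5.04 TPM in switchgrass, and TR19256__c0_g1 was listed at 0 in all 3 switchgrass libraries and was at 521 ± 35.2 TPM in control. The 10 genes chosen as most abundant in the plant libraries held 33.0% ± 13.3 of TPM in switchgrass.

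The limma log2 fold changes were 13.29 ± 0.90 for TR355__c0_g1 (adjusted p = 1.71e-08) and -9.12 ± 1.08 for TR17256__c0_g1 (adjusted p = 1.73e-05). The adjusted p was 0.000551 for TR14277__c0_g1 and 1.07e-06 for TR19256__c0_g1, with no fold against a group at 0. With median-of-ratios scaling 2399 genes were higher and 1212 lower, and the median of all tested genes moved from -0.58 to 0.09 on the log2 scale. Single libraries also moved the split: there were 674 genes higher and 567 lower without the third switchgrass library, 424 and 439 (863 in all) without the first, and 742 and 891 without the second. Without the first, the second and the third control library there were 347 and 365 (712 in all), 324 and 339 (663) and 340 and 445 (785). There were 1225 and 5632 (6857) without the third maltose library, and 3239 and 3959 with scaling as well. Under the second table's names all 4 named genes were called in the opposite direction.

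Genes called against control in poplar and in switchgrass overlapped. Among the higher genes 360 were shared (13.8 expected for independent lists) and among the lower 868 (97.8 expected). The expected counts leave out the shared controls, which are too few to split, so part of this excess may come from them. The balance of these lists depended on the processing: 1676 higher and 811 lower genes were shared with median-of-ratios scaling, 625 and 5101 without the third maltose library, 5980 and 710 under the second table's names, and 229 and 304 in a test against a 1.5-fold change. The 360 genes had a median of 54.3 TPM in poplar, 77.8 in switchgrass and 1.12 in control, and the 868 had 2.07, 2.43 and 46.1 TPM. The fold changes correlated across the 23981 genes, which are not independent replicates, with r = 0.895 (0.500 in simulations of unchanged groups against the same controls) and a covariance of 2.15 (0.343 simulated). Both comparisons also share the difference in preparation. The calls of cellobiose against control overlapped with those of poplar in 5 higher genes (1.06 expected) and 7 lower genes (1.64 expected), while 8 of the 48 higher genes and 1 of the 19 lower genes were called in the opposite direction in poplar. The correlation was 0.288 (0.501 simulated), the same-sign share 58.3% (66.7% simulated) and the covariance 0.355 (0.344 simulated). With those of switchgrass they overlapped in 5 higher (1.25 expected) and 9 lower genes (0.901 expected), with 0 and 1 in the opposite direction. There the correlation was 0.321 (0.499 simulated), the same-sign share 59.0% (66.6% simulated) and the covariance 0.392 (0.342 simulated). The simulated values follow from shared controls at a pooled spread, so lower observed correlations and shares do not show less agreement than chance. That spread may exceed the spread of the controls, so the simulated covariances may be too high.

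Switchgrass and poplar, which share a preparation, were compared directly. In switchgrass 5 genes were higher and 1 was lower. TR7964__c0_g1 was at 91.4 ± 21.8 TPM in switchgrass, 0.723 ± 0.595 in poplar and 20.9 ± 6.90 in control. TR10098__c0_g1 was listed at 0 in all 3 poplar libraries and was at 53.7, 18.45 and 29.7 TPM in switchgrass. TR14164__c0_g1, named after its values were seen, was at 17.8, 8.45 and 3.88 TPM in poplar and listed at 0 in all 3 switchgrass libraries.

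The limma log2 fold change of TR7964__c0_g1 was 5.78 ± 0.87 (adjusted p = 0.0129); the adjusted p was 0.0129 for TR10098__c0_g1 and 0.0305 for TR14164__c0_g1, and 1051 genes had an unadjusted p under 0.05. The replicates did not overlap in 4.72% of the tested genes, where chance gives at most 10%. Genes tied between the groups, as at 0, cannot count, so the chance share is lower. The 4.72% therefore does not show more likeness than chance. The count of 6 was 2, 0 and 17 without the first, the second and the third poplar library, 11 and 24 without the first and the third switchgrass library, and 26 without the third maltose library. Median-of-ratios scaling gave 34 genes higher and 76 lower, and the median of all tested genes moved from 0.27 to -0.03 on the log2 scale. Under the second table's names the 3 named genes changed sign and none of them was called. Counting that setting, the call of TR7964__c0_g1 was lost in 3 of 17 alternatives, that of TR10098__c0_g1 in 4 of 17 and that of TR14164__c0_g1 in 9 of 16.

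Glucose was compared with control through a single library. No gene was called by limma (0 calls; 460 genes at an unadjusted p under 0.05; smallest adjusted p 0.191). The glucose library lay outside the range of the control libraries in 59.1% of the tested genes, where chance gives at most 50%. Without the third maltose library 10 genes were called, 5 higher and 5 lower, with no filter on low values 16, and under the second table's names 5394.

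**Figure D2:**
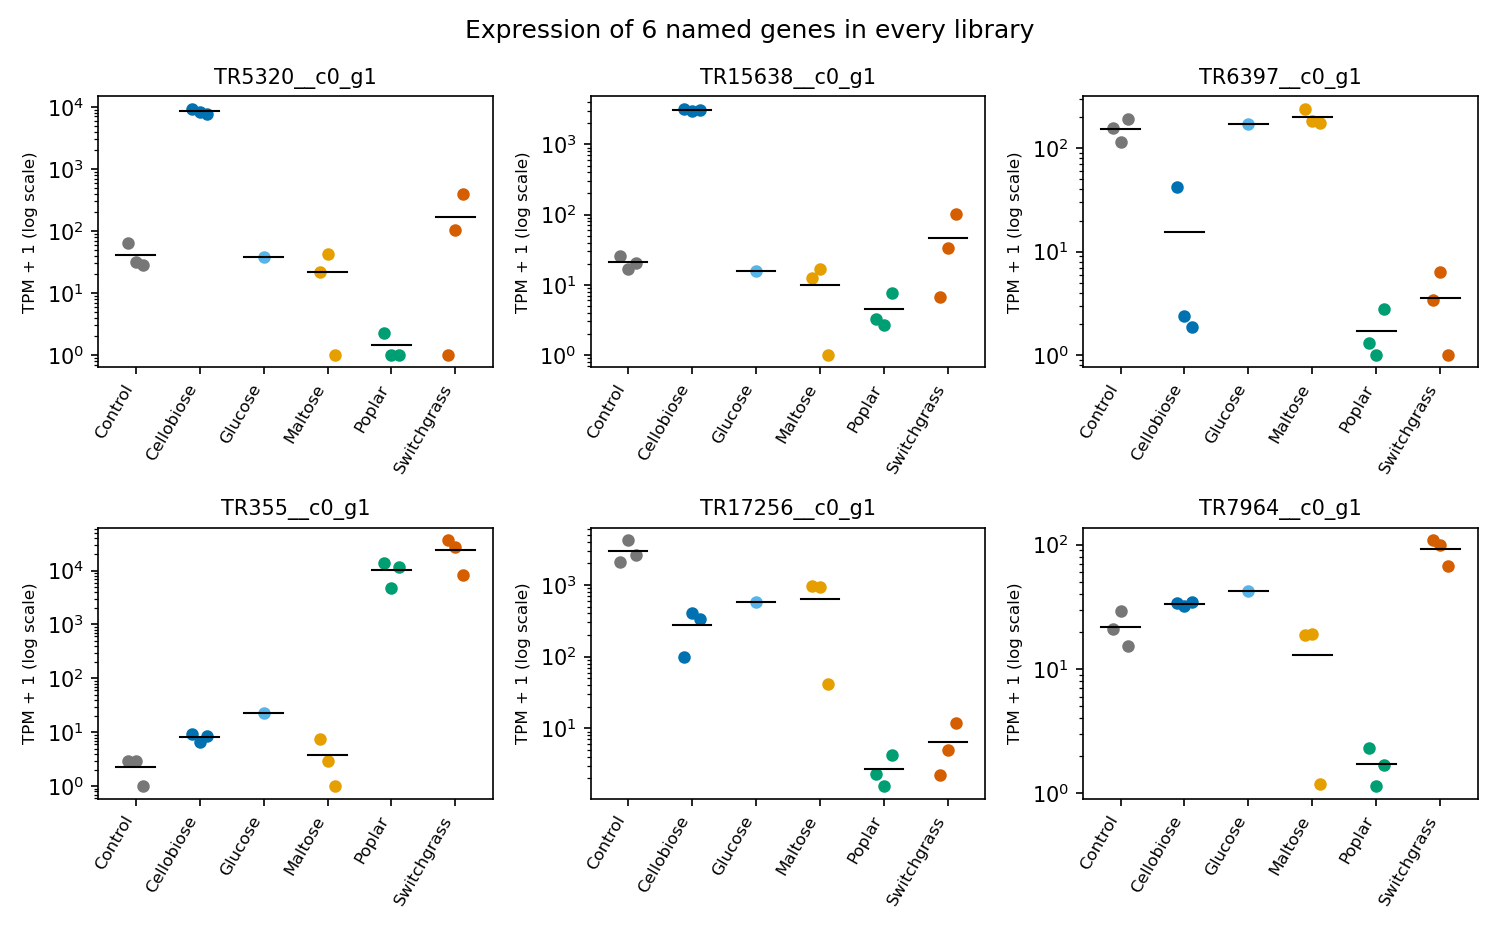
Points give TPM + 1 on a log axis for 6 named genes in each library, by group (horizontal axis; 3 libraries per group, 1 for glucose), and black lines the group means. TR5320__c0_g1 and TR15638__c0_g1 were at 8449 ± 905 and 3124.5 ± 115.1 TPM in cellobiose, and the lowest plant library of TR355__c0_g1 was at 4746 TPM.

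**Figure D3:**
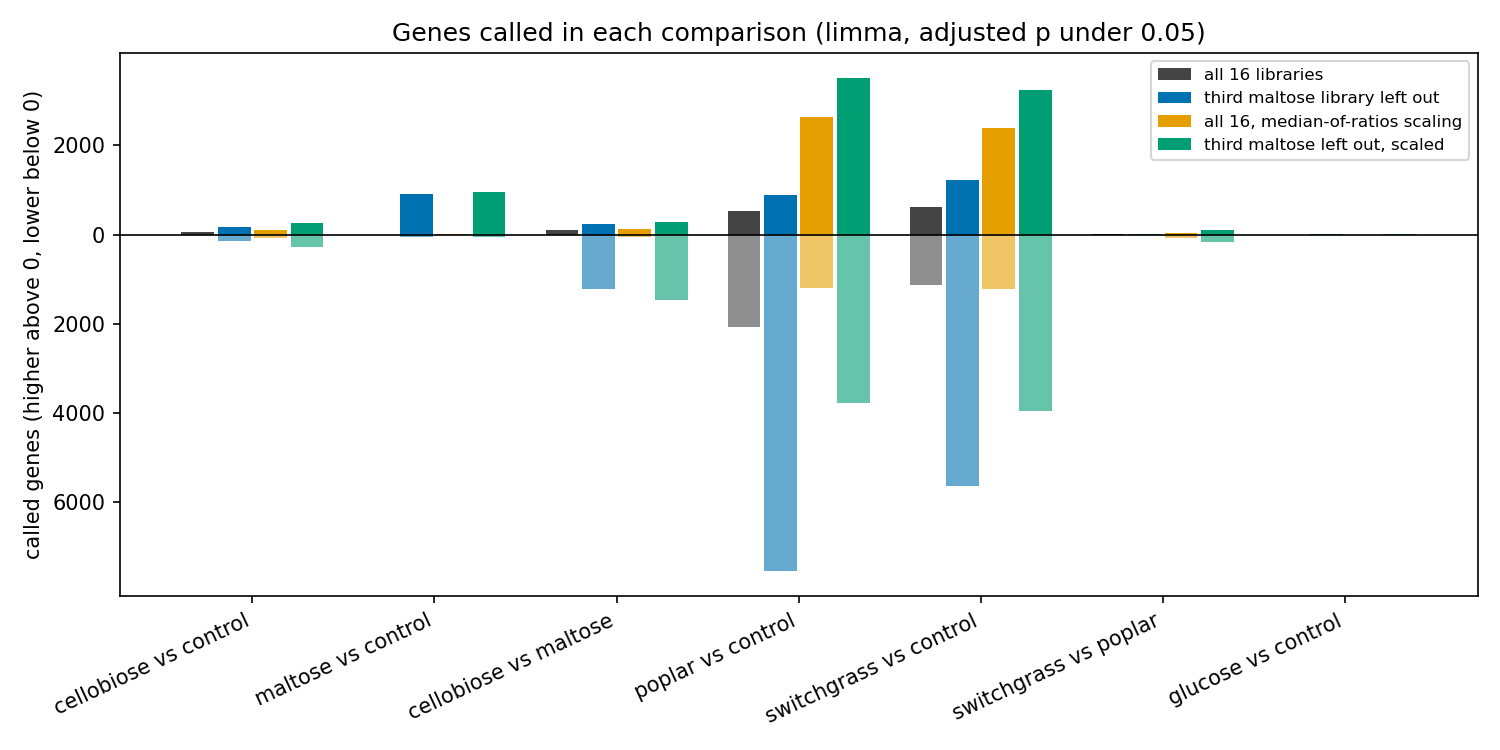
Bars give the number of genes called by limma in each comparison (vertical axis, genes; higher above 0, lower and paler below 0) for all 16 libraries, without the third maltose library, with median-of-ratios scaling, and with both. For poplar against control the lower genes were 2063 with all libraries and 7556 without the third maltose library, and scaling turned the split to 2645 higher and 1205 lower.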

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

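The tests of a header error, and of the third maltose library other than that of its remaining reads, were chosen after the results were seen, as was the test of growth on maltose for the 903 genes. The direct comparisons of sugars and of plant substrates drew attention because they test whether changes against the same control differ. Cellobiose and maltose differed in 116 genes, and switchgrass and poplar in 6.

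Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. The counts of splits that were as large or gave as many include the real split and mean at least as many calls. The real split gave 67 calls for cellobiose against control, with 0 as the highest of the others (1 split of 10 as large), 2594 for poplar against control (highest other 0; 1 split) and 1761 for switchgrass against control (highest other 0; 1 split). For maltose against control it gave 1 call, and 2 of the 10 splits gave as many; the split of the first control library with the first and second maltose libraries against the rest gave 1267. For cellobiose against maltose it gave 116, 2 splits gave as many, and the split of the first and the third cellobiose libraries with the third maltose library gave 708. For switchgrass against poplar it gave 6, 3 splits gave as many, and the split of the first and second poplar libraries with the third switchgrass library gave 181. These larger splits point to a structure of the samples that is not their group.

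In the third maltose library 10 genes held 83.7% of TPM, against 1.36% to 1.74% in the control libraries, 2.90% in the glucose library and 2.085% to 8.40% in the 6 plant libraries. Growth on maltose as the whole cause is argued against by the 0.801% that these genes held in the first maltose library, below every control library, although the second held 2.54%. A swap with a plant library is argued against by a highest correlation of 0.531 with any plant library, below the lowest with a poly-A library (0.571), and by the plant libraries, each of which correlated more with its own group than with control. On the first principal component the third maltose library (210.8) lay among the plant libraries (69.2 to 216.5). On the second it (246.5) stood apart from them (-122.1 to 36.7). A single RNA source present in every library and most abundant there would keep the 10 genes at the same ratios to each other. As a median over the other 15 libraries, the SD of their log2 ratios to the third maltose library was 0.224. The 5th percentile of random sets was 1.36. Those sets were matched on level in the other libraries only, while the 10 genes were chosen as highest in the third maltose library. Low values there can widen the random SDs, so this source stays open. Few reads left for other genes may account for many zeros of the third maltose library. Of genes at 1 to 10, 10 to 100 and over 100 TPM in the other maltose libraries, 57.2%, 17.6% and 7.70% were listed at 0 in it. The 903 genes called higher in maltose without this library argue against few reads as the cause of their own zeros. Of them 755 were listed at 0 there, at medians of 22 and 26.0 TPM in the first and second maltose libraries. With the 10 dominant genes set aside they held 0.0827% of TPM there, against 9.45% and 14.5%.

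Without that library 903 genes were higher in maltose than in control. Growth on maltose as the whole cause is argued against by the control libraries, which had no added energy source. In them the summed TPM of these genes differed 10.8-fold. Random sets reached at most 1.11-fold, but they sum genes that vary separately. They are therefore no measure for a set that varies together, and a part played by maltose is not excluded. RNA of another source mixed in varying amounts may account for them and stays open. Its test gave an SD of 0.867 for log2 ratios between cellobiose and glucose libraries, against a median of 0.853 and a 95th percentile of 0.938 for random sets. The 903 genes lay near the floor there, at library medians of 0.41 to 1.13 TPM. Of them 202 reached 1 TPM in all 3 cellobiose libraries and the glucose library. Between the second and first maltose libraries, where they were high, the SD was 0.645 for them and 0.493 for the other genes. Those other genes were not matched on level. By the bound written beforehand, an SD at or above the median counted against a mixed-in source, and 0.867 lies above the median. That bound was replaced by the 95th percentile after the result was seen, because 0.867 lies within the spread of the random sets. The change turned a result against the mixed-in source into an open one, so the test decides nothing.

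The column names of the pair of tables disagree, and which header is misplaced stays open. Correlation of libraries within a stated preparation exceeded that across preparations by 0.133 under the names used and by -0.00508 under the other names. An earlier form of this test, limited to the 6 plant-labelled libraries, went the other way (0.115 against 0.131), and the form above was chosen after that was seen. Under the other names the maltose libraries are those here named glucose and first and second maltose. They correlated at means of 0.822 to 0.879 with the libraries here named control and cellobiose, rRNA-depleted under the other names. With those here named poplar and switchgrass, poly-A under the other names, the means were 0.631 to 0.700. This argues against the other names only if preparation shapes correlation more than substrate, which was not tested. The mean correlation within groups was 0.811 under the names used and 0.849 under the other names, which leave the unusual maltose library alone as the glucose library. Without that library the values were 0.847 and 0.849. Correlation within groups can hardly tell the headers apart, because the control, cellobiose, poplar and switchgrass groups only trade names as wholes. No biological explanation was tested for this pattern.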

How the results depend on the processing

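Count-based tests, size factors, filters and fold thresholds that had been planned were not run because the tables hold no counts, and the settings planned for the fixed gene lists were not run because no list could be evaluated; stand-ins on TPM were chosen after the data were seen, as were the other settings below from scaling onward. Comparisons are given in the order cellobiose, maltose, poplar, switchgrass and glucose against control, then cellobiose against maltose and switchgrass against poplar; where one is missing from a sentence its count stayed within 1.5 times, or the setting was not run for it or is given with the libraries left out in turn. The cause of these differences was not tested unless stated. A pseudocount of 0.1 gave 9 calls for cellobiose (4 higher, 5 lower) and 43 for cellobiose against maltose; for switchgrass against poplar it gave 8 (4 higher, 4 lower), of which 2 were among the 6. Fits to the 2 groups compared, which drop the spread of the third maltose library from comparisons without maltose, gave 3197 for cellobiose, 0 for maltose, 7487 for poplar, 6923 for switchgrass, 16 for cellobiose against maltose and 25 for switchgrass against poplar. Leaving out 1 library of the compared groups gave 20 to 33 for cellobiose, 0 to 948 for maltose, 660 to 3442 for poplar, 663 to 1633 for switchgrass, 0 to 0 for glucose, 47 to 1456 for cellobiose against maltose and 0 to 24 for switchgrass against poplar. The highest values for maltose (948) and for cellobiose against maltose (1456) came without the third maltose library.

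Replicate numbers do not pair the libraries: 2 of 30 same-number pairs correlated above 0.1, and 1 of 15 libraries correlated best with its own number. With the replicate number as a block the counts were 43, 0, 1987, 1568, 0, 100 and 4.

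Median-of-ratios scaling gave 173 calls for cellobiose, 10 for maltose, 3611 for switchgrass and 110 for switchgrass against poplar, and 3850 for poplar. Of the main calls it kept 46 of 67 for cellobiose, 1 of 1 for maltose, 1512 of 2594 for poplar and 1278 of 1761 for switchgrass. It kept 82 of 116 for cellobiose against maltose and 6 of 6 for switchgrass against poplar. With no filter on low values maltose had 0 and glucose 16, and with at least 10 TPM in 3 libraries maltose had 0. Testing against a 1.5-fold change, a stricter null, gave 28, 0, 1007 and 813 for the first 4 comparisons and 68 for cellobiose against maltose. Testing transcripts gave 113 for cellobiose, 3 for maltose, 185 for cellobiose against maltose and 10 for switchgrass against poplar. Without the third maltose library the counts were 314 for cellobiose, 8435 for poplar, 6857 for switchgrass, 10 for glucose and 26 for switchgrass against poplar; this removes the spread that library adds to the shared estimate. All 67, 2594, 1761 and 6 genes called in the corresponding main tests were among them. Without it and with scaling they were 543, 1006, 7294, 7198, 22, 1750 and 273. Without it and the second poplar library poplar had 6717 and switchgrass against poplar 31. Estimated weights per library gave 3653, 6708, 17877, 9407, 668, 9586 and 4124, but their estimation did not converge (weights from 0.0166 for the third maltose library to 104.6 for the first poplar library), so these counts carry no weight.

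Under the second table's column names the counts were 43, 9206, 8304, 8299, 5394, 7912 and 340. The fitted log2 differences that changed sign there were 0.12 for TR4168__c0_g1 in cellobiose, 1.45 for TR14662__c0_g1 in maltose, -10.16 for TR355__c0_g1, -11.68 for TR15843__c0_g1, 6.60 for TR17256__c0_g1 and 6.42 for TR5381__c0_g1 in poplar, -12.14 for TR355__c0_g1, -8.52 for TR14277__c0_g1, 10.19 for TR17256__c0_g1 and 7.42 for TR19256__c0_g1 in switchgrass, and -0.67 for TR7964__c0_g1, -1.14 for TR10098__c0_g1 and 1.35 for TR14164__c0_g1 in switchgrass against poplar. Of these, the values of TR14662__c0_g1, TR14277__c0_g1 and TR14164__c0_g1 set a group against one listed at 0 throughout, so the pseudocount sets their size and they are no folds. The first of the 13, that of TR14662__c0_g1 and the 3 of switchgrass against poplar were not called (5 in all), and the other 8 were called. Over the alternatives other than the library weights, named genes kept direction and call in 244 cases, kept direction but lost the call in 64 and changed sign in these 13. Depth is unknown, so its limits on these values could not be given.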

Other observations

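The 10 genes most abundant over the poly-A libraries held 10.9% ± 0.405 of TPM in cellobiose (SD, n = 3), 6.98% ± 1.18 in control and 2.28% ± 0.863 in switchgrass. They held 6.08%, 7.19% and 17.85% in the 3 maltose libraries and 3.82%, 14.5% and 1.68% in the 3 poplar libraries. The 868 genes called lower in both plant substrates, and so low there by choice, held 13.3% of TPM in control, 8.55% in cellobiose and 0.587% in poplar. Both fractions rest on TPM, in which a rise of abundant genes lowers all others.

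The comparisons glucose against maltose and cellobiose against glucose were tried after the data were seen. The first gave 0 calls by limma (591 genes at an unadjusted p under 0.05) and the second 12 (9 higher and 3 lower in cellobiose). The first principal component held 47.2% of the variance and the second 20.1%. On the first, the third maltose library (210.8) lay with the 6 plant libraries (69.2 to 216.5) and the other poly-A libraries lay between -133.2 and -91.6. On the second, the third maltose library (246.5) lay apart from the plant libraries (-122.1 to 36.7) and the other poly-A libraries (-9.84 to 57.4).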
